A study of Drosophila melanogaster with 12 samples.

How the data were processed

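The samples were 12 pools of 115 fluorescent neurons sorted from dissociated adult Drosophila melanogaster brains, at least 15 brains per pool, 3 pools for each of 4 groups: dopaminergic and cholinergic neurons from controls and from parkin null mutants. Brains were treated with trypsin in a warm incubation, and green fluorescent cells were sorted into lysis buffer. Per the labels, cDNA was amplified with the Ovation One-Direct kit, labelled with biotin and hybridised to Affymetrix Drosophila 2.0 arrays, with 1 array per pool. The deposited values were log2 intensities per probe set, normalized and summarised by the authors with a method not given in the sources used here. Array medians ran from 5.59 to 6.30, so the summarised values did not have the same distribution on every array. This does not show whether quantile normalization was used before summarising.

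The table held 18952 probe sets, of which 183 were control probe sets and were left out, leaving 18769. The annotation table paired 13647 of these with 1 gene symbol, 402 with several and 4720 with none, and 13544 of the single symbols matched the reference gene table for the Release 6 assembly, which was used only for names and for where genes lie. Only probe sets with 1 symbol were named. Probe sets at or above the median of their own array on at least 3 arrays were kept, which left 12460. Values were used as deposited, without further scaling.

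Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend on mean level, 2-sided) on all 12 arrays with 1 coefficient per group, so that all groups shared 1 estimate of the spread. The 5 comparisons were mutant minus control in each neuron type, the difference of those effects (dopaminergic minus cholinergic), dopaminergic minus cholinergic in controls, and the mutant effect averaged over neuron types. p-values were adjusted by the method of Benjamini and Hochberg within each comparison, with a threshold of 0.05. Standard errors (SE) are those of limma. The prior had 3.07 degrees of freedom beside 8 residual ones.

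In all, 31 gene lists were fixed: markers of transmitter types, peptidergic neurons, Kenyon cells and other cell types, mitochondrial and energy pathways, proteostasis and stress pathways, and synaptic, channel, clock and ribosomal genes. They were tested with camera at a preset correlation between genes of 0.01, with 1 probe set per gene (the highest mean), over 7613 genes. The 27 lists with at least 5 tested genes were tested. Members without a named probe set could not be tested. Only 10 of 22 heat shock and chaperone genes and 10 of 19 photoreceptor genes had one. The cholinergic, GABA and glutamate, serotonin and octopamine, and hemocyte lists had fewer, and values of some members are given in place of a test. Camera compares a list with the other genes, so its calls are relative to any shift shared by all genes. Camera with an estimated correlation and fry were run as alternatives.

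The groups, comparisons, lists, tests and alternatives were fixed before the data were examined, except where an alternative is said to be added later. Genes were named by rule. The parkin gene came first, then up to 10 genes in each direction past the threshold without overlap between groups. Where fewer passed, the genes with the smallest p were added up to 5 per direction and are named as not passing. Up to 4 members with the smallest p in each list could be named, and ple, Vmat, DAT, ChAT and VAChT were followed in every group. No probe set was named for parkin in the annotation used, so it was not analysed here.

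Alternatives were quantile normalization, centring of arrays, no filter, a filter at the 65th percentile, eBayes without a trend or with robust hyperparameters, array weights, only the 6 arrays compared, codes in the sample titles as blocks, the mean of a gene's probe sets, an adjusted p threshold of 0.1, and leaving out each array in turn. The meaning of the title codes is not given. The labels do not say whether the pools of a group came from separate cohorts of flies, so p-values measure only the spread between these arrays, and the number of arrays limits the precision.

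The tests were tested on data simulated from the residuals of these arrays, over 10 simulations with a change in the dopaminergic mutants. A log2 change of 2 was recovered for 13.1% of changed probe sets, a change of 4 for 55.8% and a change of 6 for 73.2%, and 9.00% of calls were probe sets with no simulated change. The autophagy and lysosome list, lowered by a log2 value of 1, was called in 6 of 10 simulations. Residuals were resampled for each probe set on its own, which removes correlation between genes and any effect of a whole array. In the data the estimated correlation reached 0.61 for the dopamine list in dopaminergic mutants. The simulations therefore do not show how the list tests behave on these arrays. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for annotation and plots.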

Results

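Gene expression was measured in dopaminergic and cholinergic neurons from the brains of control flies and of flies lacking parkin, a ubiquitin ligase of mitochondrial quality control whose loss causes an inherited form of Parkinson's disease. The series title sets sensitive against insensitive neuron populations. Each of the 4 groups had 3 arrays, each from 115 sorted neurons. Replicates of a group correlated little more with each other (median r = 0.640) than with arrays of other groups (median r = 0.625, across probe sets, which are not independent). Dopaminergic mutant replicate 3 stood apart. Its correlation with the other arrays ran from 0.263 to 0.532, and it had 1627 probe sets at or above a log2 value of 8, against 2182 to 3307 on the others. Of 410 probe sets bright on at least 10 other arrays it had lost 212 (51.7%), against 29 of 319 (9.09%) in dopaminergic mutant replicate 1 and at most 5 on any other array. The neuronal gene elav measured 6.27 on that array and 9.07 to 11.90 on the others, while the neuronal gene nSyb was little lower (10.65 against 10.70 to 11.61).

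**Figure D1:**
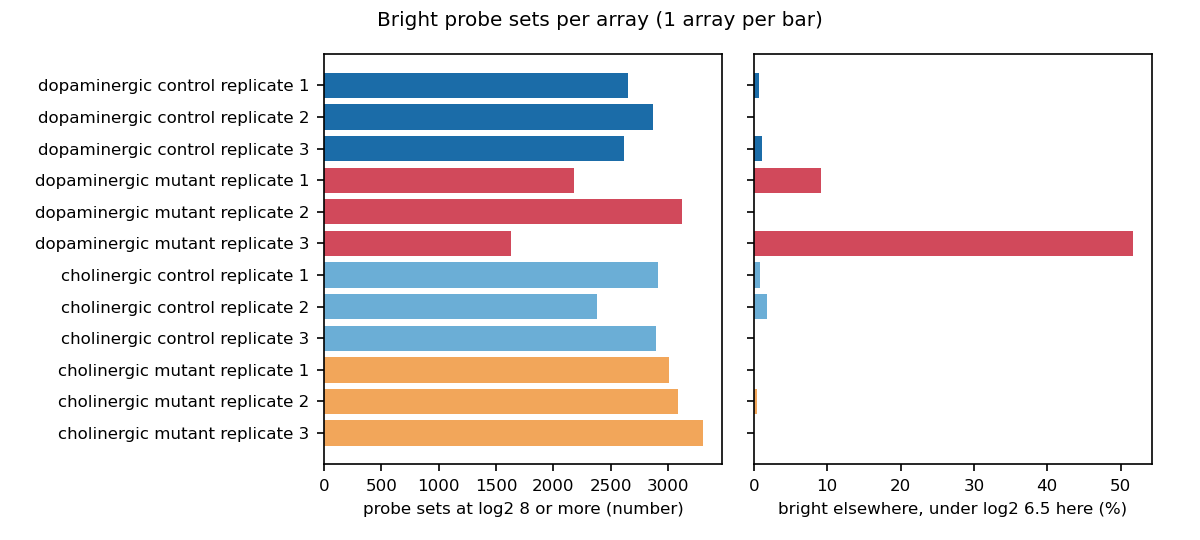
For each of the 12 arrays, the number of probe sets at or above a log2 value of 8 and the share of probe sets bright elsewhere that were lost on that array. Dopaminergic mutant replicate 3 has 1627 bright probe sets and lost 51.7%.

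The comparison of neuron types in controls asked whether the sorts differed in their transmitter genes. Dopaminergic pools had higher levels of all 5 tested genes of dopamine synthesis and handling, by a mean log2 difference of 3.79 (adjusted p = 4.72e-05 for the list; adjusted p = 0.666 with an estimated correlation, and 0.0178 with an estimated correlation without dopaminergic mutant replicate 3; n = 3 per group). Adjusted over the list alone, 2 members were higher. The tyrosine hydroxylase gene ple measured 10.50 ± 0.10 (SD, n = 3) in dopaminergic and 3.85 ± 0.30 in cholinergic controls. The log2 difference was 6.65 ± 1.19 (SE) for ple, 4.78 ± 1.65 for the dopamine transporter DAT, 3.49 ± 1.94 for the vesicular monoamine transporter Vmat and 2.11 ± 1.22 for the decarboxylase Ddc. Since the groups share 1 estimate of the spread, the SE of ple also reflects the dopaminergic mutants (SD 3.31), which are not compared here. Fer2, a transcription factor of dopaminergic neurons, differed by 4.83 ± 0.77 (10.24 against 5.41; adjusted p = 0.149).

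No single probe set passed among 12460 with limma (452, or 3.63%, at an unadjusted p under 0.05; smallest adjusted p = 0.119). The genes with the smallest p, none of which passed, included CG12868 (4.56 ± 0.72), trus (3.98 ± 0.74) and Oct-TyrR, a receptor for octopamine and tyramine (3.21 ± 0.55), all measured higher in dopaminergic controls. In the other direction, the differences were −4.22 ± 0.55 for the Notch target E(spl)m5-HLH, −4.02 ± 0.68 for Vps11, −5.33 ± 1.08 for the axon guidance gene beat-Ia and −5.80 ± 1.19 for fs(1)K10. beat-Ia was also measured lower in the dopaminergic mutants (3.22 against 7.51 in cholinergic mutants). The cholinergic genes did not separate the sorts. ChAT, which makes acetylcholine, differed by 0.24 ± 1.26, and its transporter VAChT by −1.20 ± 1.16. The count of probe sets was 4 without cholinergic control replicate 1, 2 without cholinergic control replicate 3, 1 without dopaminergic control replicate 1, 4 without dopaminergic control replicate 3 and 5 without dopaminergic mutant replicate 2. The dopamine list was called without each array in turn, and the other 26 lists were not called (adjusted p from 0.407 to 0.985). Among the photoreceptor genes, 1 was lower adjusted over the list alone (rdgB, −2.88 ± 0.85). For lists too short to test, the mean levels in dopaminergic and cholinergic controls were 4.71 and 8.59 for the glutamate transporter VGlut, 6.89 and 7.30 for the octopamine synthesis gene Tbh, and 4.90 and 5.49 for the hemocyte gene Pxn.

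**Figure D2:**
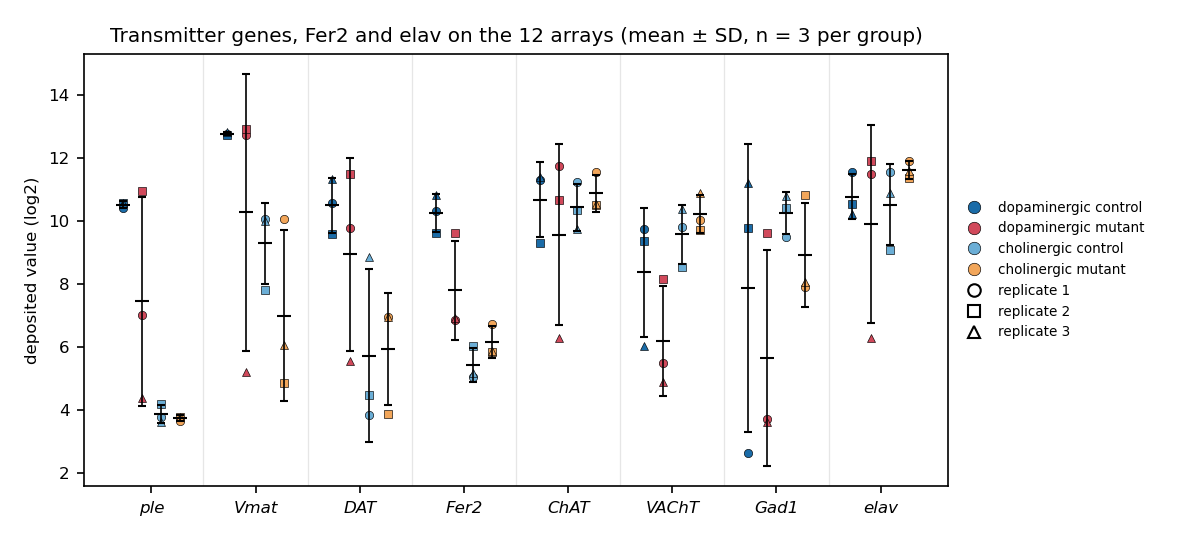
Deposited log2 values of transmitter and neuronal marker genes on each array (points, by group and replicate), with the mean and SD of each group (n = 3). ple lies between 10.39 and 10.57 in dopaminergic controls and between 3.61 and 4.18 in cholinergic controls.

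The effect of the parkin mutation in dopaminergic neurons, the type that degenerates in Parkinson's disease, was examined first by gene and then by list. No probe set changed past the threshold with limma (0 of 12460; 560, or 4.49%, at an unadjusted p under 0.05; smallest adjusted p = 0.330). The 3 genes with the smallest p were measured lower in mutants, without overlap between groups. They were also named in the comparison of neuron types in controls, which uses the same 3 dopaminergic control arrays. The results for these genes are therefore not independent. CG12868 measured 9.96 ± 1.72 (SD, n = 3) in controls and 5.38 ± 0.42 in mutants, a log2 difference of −4.58 ± 0.72 (SE). The difference was −3.83 ± 0.74 for trus, −2.74 ± 0.55 for Oct-TyrR (both adjusted p = 0.728), −5.77 ± 1.31 for Mob2, an adaptor of protein kinases, and −5.40 ± 1.24 for CG7069. In mutants, higher values were measured for the tetraspanin Tsp42El (1.89 ± 0.40), the translation initiation factor subunit eIF3g2 (1.89 ± 0.46), PPYR1 (1.64 ± 0.41), the kinase gene Cdc2rk (2.25 ± 0.58) and CG31301 (2.95 ± 0.79). None of these 10 genes passed (adjusted p from 0.330 to 0.782), and chance alone separates 3 arrays from 3 in 10% of genes. A different probe set for Mob2 gave −1.71.

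Without dopaminergic mutant replicate 3 these genes kept their sign, with −4.57 for CG12868, −3.96 for trus, −2.95 for Oct-TyrR and 1.83 for Tsp42El, and none passed. The count of probe sets was 74 without dopaminergic mutant replicate 2, 2 without dopaminergic control replicate 3 and 1 without dopaminergic control replicate 1. Of the 74, 70 were lower in mutants. The mutant arrays left there, replicates 1 and 3, had lost the most bright probe sets (9.09% and 51.7%). The count was 524 with array weights, where the mutant side rests mostly on dopaminergic mutant replicate 1 (weight 4.56, against 0.28 and 0.41 for replicates 2 and 3). Over all tested probe sets the median log2 difference was 0.18 in dopaminergic and −0.17 in cholinergic neurons. It was 0.26 for the difference of the effects.

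As lists, 10 of 27 passed in dopaminergic mutants, 9 lower and 1 higher, against a mean of −0.11 over all 7613 genes. None of the 10 passed with an estimated correlation (smallest adjusted p = 0.328) or with fry (smallest adjusted p = 0.178). None passed without dopaminergic mutant replicate 3 (smallest adjusted p = 0.303), and 5 passed without dopaminergic control replicate 3. The plot of list means with and without dopaminergic mutant replicate 3 shows the size of that dependence.

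All 5 tested genes of dopamine synthesis and handling were lower in dopaminergic mutants, by a mean log2 difference of −2.13 (adjusted p = 0.0112; adjusted p = 0.439 with an estimated correlation). The mean was −0.14 without dopaminergic mutant replicate 3. The difference was −3.07 ± 1.19 (SE) for ple, −2.50 ± 1.94 for Vmat, −1.85 ± 1.22 for Ddc and −1.56 ± 1.65 for DAT. On the 3 mutant arrays ple measured 7.01, 10.94 and 4.36, and Vmat 12.71, 12.90 and 5.19. With the last of these arrays left out the difference was −1.53 for ple, and the sign turned for Vmat (0.039) and DAT (0.13).

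Heat shock and cytosolic chaperone genes were lower in 9 of 10 cases (mean −1.36; adjusted p = 0.00429; adjusted p = 0.439 with an estimated correlation). Only 10 of the 22 genes of this list had a named probe set, and Hsp83, Hsp22, Hsp23 and the genes Hsp70Aa to Hsp70Bc had none. The small heat shock proteins Hsp27 and Hsp26 differed by −2.28 ± 0.88 and −1.94 ± 0.89, and the Hsp40 co-chaperone DnaJ-1 by −2.42 ± 1.36. The list mean was −0.24 without dopaminergic mutant replicate 3, with Hsp27 at −1.30, Hsp26 at −0.67 and DnaJ-1 at −0.28.

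The lists of synaptic vesicle release, Kenyon cell markers and activity or dissociation genes were also lower. Those of neuropeptides and voltage-gated channels did not pass. For synaptic vesicle release 15 of 19 genes were lower (mean −1.19; adjusted p = 0.00587; adjusted p = 0.439 with an estimated correlation). The synaptic genes with the smallest p were the synapsin gene Syn (−4.19), the SNARE gene Snap25 (−4.24 ± 1.59), unc-13 (−2.42 ± 1.21) and the active zone gene brp (−2.30 ± 1.21). Syn, Snap25 and unc-13 were low on dopaminergic mutant replicates 1 and 3 but not on replicate 2 (Snap25 5.72, 11.58 and 3.85). All 7 Kenyon cell genes were lower (mean −1.72; adjusted p = 0.00429; adjusted p = 0.328 with an estimated correlation), among them the adenylyl cyclase gene rut (−2.70 ± 1.23) and the dopamine receptor gene Dop1R1 (−1.75 ± 1.00). Of 8 genes responsive to neuronal activity or dissociation 7 were lower (mean −1.62; adjusted p = 0.0111; adjusted p = 0.439 with an estimated correlation), as for cbt (−2.25) and the nuclear receptor gene Hr38 (−1.82). The means of these 3 lists were −0.36, −1.10 and −0.27 without dopaminergic mutant replicate 3, with Syn at −3.44, Snap25 at −2.64, unc-13 at −1.60 and rut at −2.82.

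The autophagy and lysosome list and the apoptosis and JNK list measured lower, while the proteasome list did not pass. For autophagy and lysosome 21 of 31 were lower (mean −0.88; adjusted p = 0.00725; adjusted p = 0.391 with an estimated correlation), with the autophagy kinase gene Atg1 at −3.12 ± 1.06, the proton pump subunit Vha26 at −4.20 ± 1.43 and Lamp1 at −4.14 ± 1.48. For apoptosis and JNK signalling 11 of 14 were lower (mean −1.05; adjusted p = 0.0220; adjusted p = 0.391 with an estimated correlation), with the JNK gene bsk at −3.41 ± 0.97 and the JNK phosphatase puc at −2.23. The means were −0.47 and −0.41 without dopaminergic mutant replicate 3, with Atg1 at −3.14, Vha26 at −3.05, Lamp1 at −2.85 and bsk at −2.83. None of these genes passed with or without that array. On dopaminergic mutant replicate 2, Vha26 (12.07) and Lamp1 (11.79) were not below the lowest control, while Atg1 (6.58) and bsk (8.63) were. Without replicate 3, the differences of Vha26 and Lamp1 thus come from replicate 1 (6.16 and 5.54).

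In metabolism and translation, 9 of 12 genes of the TCA cycle and pyruvate dehydrogenase were lower (mean −0.88; adjusted p = 0.0243; adjusted p = 0.391 with an estimated correlation), and 1 member, the succinyl-CoA ligase subunit Scsalpha1 (−2.77 ± 0.74), was lower adjusted over the list alone. Of 37 cytosolic ribosomal protein genes 26 were lower (mean −0.65; adjusted p = 0.0220; adjusted p = 0.439 with an estimated correlation), as for RpS30 (−1.87). Of 56 mitochondrial ribosomal protein genes 42 were higher (mean 0.40; adjusted p = 0.00725; adjusted p = 0.439 with an estimated correlation), as for mRpS24 (1.27 ± 0.42) and mRpS11 (3.38 ± 1.24). Leaving out dopaminergic mutant replicate 3 gave means of −0.54, −0.12 and 0.28. The 17 lists that did not pass had adjusted p from 0.0848 to 0.970. They included mitochondrial chaperones and proteases (mean −0.80), the PINK1-parkin pathway (−0.70; 12 of 17 lower), oxidative phosphorylation (−0.19; 28 of 53 higher), innate immune response (0.54), glycolysis (−0.13), proteasome (−0.32), oxidative stress and glutathione (0.14), the ATF4 list (−0.07), iron and iron-sulfur genes (−0.39) and the circadian clock (−0.31). Markers of glia (0.23), photoreceptors (−0.96), fat body (0.31) and muscle (0.47), neuropeptides (−0.13), sex-biased transcripts (−0.18) and voltage-gated channels (−0.27) did not pass either. The photoreceptor median (0.28) had the opposite sign to its mean, as had the medians of the glial, neuropeptide, sex-biased, oxidative phosphorylation, glycolysis, ATF4 and iron lists.

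**Figure D3:**
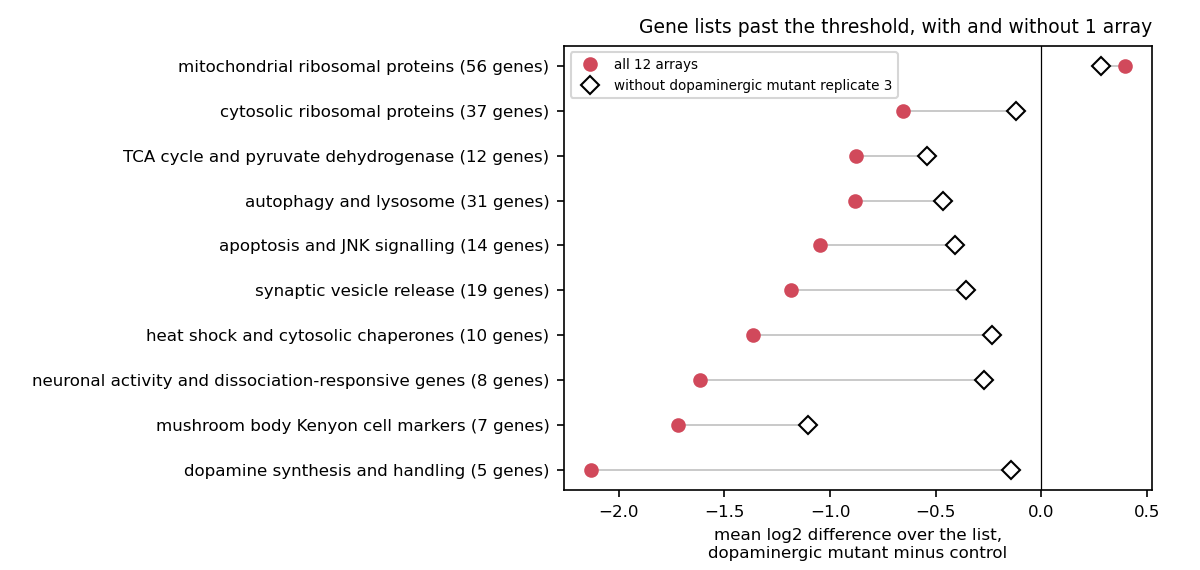
Mean log2 difference (dopaminergic mutant minus control) over the genes of each of the 10 lists past the threshold, with all 12 arrays (filled circles) and without dopaminergic mutant replicate 3 (open diamonds). Every diamond lies nearer to 0 than its circle, and the dopamine list moves from −2.13 to −0.14.

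In cholinergic neurons 6 of 12460 probe sets differed between mutants and controls past the threshold with limma, 4 higher in mutants and 2 lower (569, or 4.57%, at an unadjusted p under 0.05). CG32246 rose from 3.70 ± 0.21 (SD, n = 3) to 8.45 ± 0.50, a log2 difference of 4.75 ± 0.48 (SE; adjusted p = 0.0103), and measured 3.49 to 4.77 on the 9 other arrays of all groups. The noncoding transcript lncRNA:CR33942 rose by 3.47 ± 0.46 (adjusted p = 0.0426), and the selenophosphate synthetase gene Sps2 by 3.16 ± 0.44 (adjusted p = 0.0430). The other probe set higher in mutants had no single gene name (3.83 ± 0.54). Vps11, a subunit of the complexes that tether endosomes and lysosomes, fell from 9.44 ± 1.55 to 3.61 ± 0.44, a difference of −5.84 ± 0.68 (adjusted p = 0.0201), and E(spl)m5-HLH fell from 8.84 ± 1.04 to 4.78 ± 0.70 (−4.06 ± 0.55; adjusted p = 0.0426). The values of mutants and controls did not overlap for any of the 5 named genes, but the naming rule required this, so it adds no support. Vps11 and E(spl)m5-HLH were also named in the comparison of neuron types in controls. That comparison uses the same 3 cholinergic control arrays, so the results are not independent. The plot of called genes by array shows that CG32246, lncRNA:CR33942 and Sps2 were high in cholinergic mutants alone among the groups and E(spl)m5-HLH in cholinergic controls alone.

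Genes next in order that did not pass were the glutamate receptor gene Ekar (3.74 ± 0.60; adjusted p = 0.0885), the small GTPase gene Ras64B (4.35 ± 0.75), mRpL20 (−3.97 ± 0.78), fs(1)K10 (−5.86 ± 1.19) and mthl7 (−4.88 ± 0.99, with −0.63 at a different probe set). The calls depended on which arrays were used. The count was 0 without cholinergic mutant replicate 1 or 2, 14 without cholinergic mutant replicate 3, 2 without cholinergic control replicate 2, dopaminergic control replicate 1 or dopaminergic mutant replicate 1, and 1 without dopaminergic control replicate 2 or dopaminergic mutant replicate 2 or 3. It was also 0 with the title codes as a block or a filter at the 65th percentile. Cholinergic control replicates 1 and 2 carry D codes (D1.12.1 and D2.12.1), while no cholinergic mutant does (C3, E4 and E6). The D codes thus partly follow genotype here, and these calls cannot be told apart from a difference between codes. The called probe sets changed too. Of the 6 called with all arrays, 1 was kept without cholinergic control replicate 1 and 4 without cholinergic mutant replicate 3. Without cholinergic control replicate 3 or dopaminergic control replicate 3, 3 were kept. Over 23 alternatives at a threshold of 0.05, CG32246 passed in 18, Vps11 in 12, E(spl)m5-HLH in 8, lncRNA:CR33942 in 7 and Sps2 in 3, and none changed sign.

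**Figure D4:**
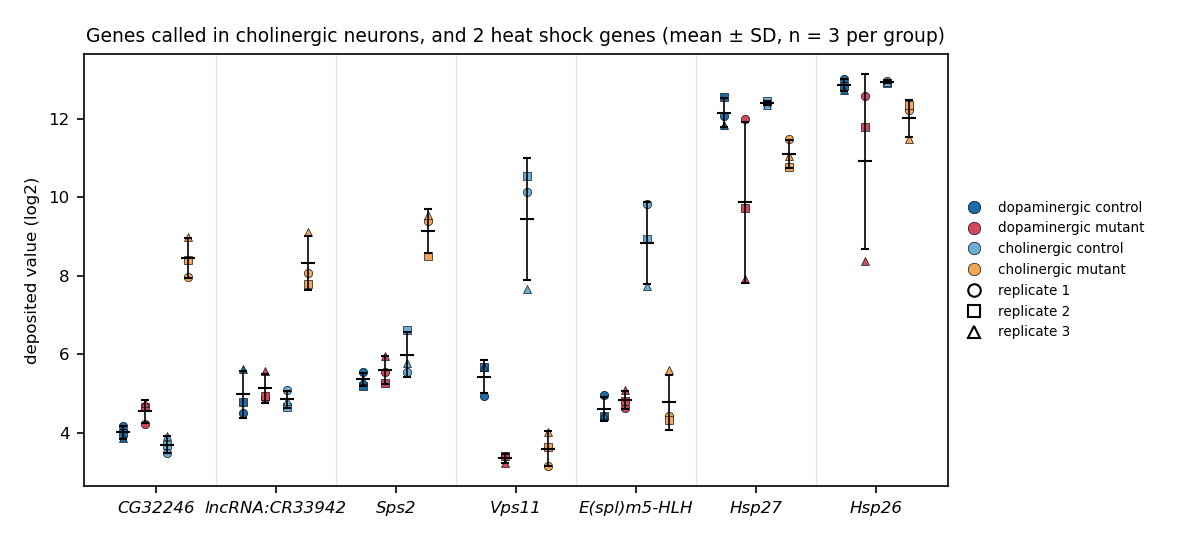
Deposited log2 values of the 5 named genes called in cholinergic neurons and of Hsp27 and Hsp26 on each array (points, by group and replicate), with the mean and SD of each group (n = 3). CG32246 lies between 7.98 and 8.98 in cholinergic mutants and between 3.49 and 4.77 on the other arrays.

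No list passed in cholinergic mutants with limma camera (0 of 27, and 0 at an unadjusted p under 0.05; adjusted p from 0.679 to 0.982), nor with an estimated correlation or fry. Heat shock and cytosolic chaperone genes measured lower in 9 of 10 cases (mean −0.49; adjusted p = 0.679), and this list alone passed when dopaminergic mutant replicate 3 was left out of the shared spread (adjusted p = 0.0220; adjusted p = 0.850 with an estimated correlation there). Hsp27 measured 12.36 to 12.46 in cholinergic controls and 10.76 to 11.49 in mutants (−1.30 ± 0.88), and Hsp26 12.90 to 12.97 and 11.47 to 12.34 (−0.92 ± 0.89). Of the genes for synaptic vesicle release 14 of 19 were higher (mean 0.42), of innate immune genes 9 of 13 lower (−0.62) and of oxidative phosphorylation genes 28 of 53 higher (0.28), none of these lists passing. Mitochondrial ribosomal protein genes were evenly split (26 higher, 30 lower), and 1 was lower adjusted over the list alone (mRpL20).

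The difference of the mutant effects asked whether the neuron types responded differently. No probe set passed with limma (0 of 12460; 645, or 5.18%, at an unadjusted p under 0.05; smallest adjusted p = 0.326). The count was 1 without cholinergic mutant replicate 1 and 3 without dopaminergic mutant replicate 2. Among genes that did not pass, the difference was −6.96 ± 1.09 for rgn, which measured 10.35 in dopaminergic controls and 7.37 in mutants but 6.38 and 10.35 in the cholinergic groups. It was −4.21 ± 0.68 for CG32246, −8.25 ± 1.47 for CG7058, −4.33 ± 0.78 for Oct-TyrR and −3.32 ± 0.66 for lncRNA:CR33942. Positive differences were 4.28 ± 0.78 for E(spl)m5-HLH, 7.08 ± 1.68 for fs(1)K10, 5.30 ± 1.27 for CG14074, 3.77 ± 0.96 for Vps11 and 2.14 ± 0.57 for Tsp42El. The 5 named genes called in cholinergic neurons did not pass this test of the difference between neuron types.

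By list, 4 of 27 passed for the difference of the effects, all lower in dopaminergic neurons. Kenyon cell genes had a mean difference of −2.40 (7 of 7 lower; adjusted p = 0.0154; adjusted p = 0.326 with an estimated correlation), with Dop1R1 at −4.34 ± 1.42. For synaptic vesicle release it was −1.61 (17 of 19; adjusted p = 0.0161; adjusted p = 0.700 with an estimated correlation), with Snap25 at −4.58 ± 2.25. For activity and dissociation genes it was −2.31 (8 of 8; adjusted p = 0.0321; adjusted p = 0.700 with an estimated correlation) and for autophagy and lysosome −1.19 (23 of 31; adjusted p = 0.0321; adjusted p = 0.481 with an estimated correlation), with Atg1 at −4.13. Without dopaminergic mutant replicate 3 none passed, and the means were −1.79, −0.78, −0.96 and −0.78. Without cholinergic mutant replicate 2 also 0 lists passed. The count was 1 without cholinergic control replicate 2, 2 without dopaminergic control replicate 3 and 7 without cholinergic control replicate 3. Innate immune genes were higher in 12 of 13 cases without passing (mean 1.16; adjusted p = 0.0665), as for the receptor gene Tl (3.08) and the attacin AttD (1.69), and the 23 lists that did not pass had adjusted p from 0.0555 to 0.977. Adjusted over the list alone, 1 ion channel gene was lower (Ca-alpha1D, −6.59 ± 1.61).

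Averaged over neuron types, heat shock and cytosolic chaperone genes were lower in mutants, 9 of 10 of them, by a mean log2 difference of −0.93 (adjusted p = 0.00564; adjusted p = 0.806 with an estimated correlation). Hsp27 differed by −1.79 ± 0.62 (SE; 6 arrays against 6), Hsp26 by −1.43 ± 0.63, the co-chaperone gene stv by −1.40 and the Hsp70 family gene Hsp68 by −0.70. Without dopaminergic mutant replicate 3 the mean was −0.37 (adjusted p = 0.0440; adjusted p = 0.945 with an estimated correlation there), and with the D title codes as a block it was −0.64 (adjusted p = 0.144). Some of these genes were bright in controls of both neuron types (Hsp68 12.88 to 13.27, Hsp26 12.72 to 13.01), while l(2)efl was not (5.89 to 7.07). Whether the warm incubation of the brains affected this list, and equally in all pools, was not tested. No probe set passed with limma (0 of 12460; 465, or 3.73%, at an unadjusted p under 0.05). The smallest adjusted p was 0.0532, for both Vps11 (−3.95 ± 0.48) and CG32246 (2.64 ± 0.34). Vps11 measured 5.42 in dopaminergic controls and 3.36 in mutants. Next in order were lncRNA:CR33942 (1.81 ± 0.33), Sps2 (adjusted p = 0.408), CG9945 (2.30 ± 0.49), Ekar (1.91 ± 0.43), E(spl)m5-HLH (−1.92 ± 0.39), Mob2 (−4.55 ± 0.93), CG12868 (−2.35 ± 0.51) and mthl7 (−2.96 ± 0.70), none of which passed. The count of probe sets was 11 without dopaminergic mutant replicate 2 (9 of them lower), 7 without cholinergic mutant replicate 3 and 1 without cholinergic control replicate 3 or dopaminergic control replicate 1. The other 26 lists did not pass (adjusted p from 0.107 to 0.957). The count of lists was 9 without dopaminergic mutant replicate 2 and 2 without cholinergic control replicate 1 or dopaminergic control replicate 2.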

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

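Of the tests below, those of a low-yield library and of a cholinergic sample under a dopaminergic label were chosen only after the result was seen. The test of the difference between neuron types passed for 4 lists at the preset correlation: Kenyon cell markers (mean log2 difference −2.40; adjusted p = 0.326 with an estimated correlation), activity and dissociation genes (−2.31; 0.700), synaptic vesicle release (−1.61; 0.700) and autophagy and lysosome (−1.19; 0.481). None of them passed with an estimated correlation, with fry, without dopaminergic mutant replicate 3 or without cholinergic mutant replicate 2. Among 100 splits drawn within neuron types, 20 gave as many lists (real value 4, highest other 8), so chance cannot be excluded. For probe sets the real value was 0 (highest other 5), which all 100 splits reach by construction, so the splits say nothing there.

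These 4 lists and the 10 lists called in dopaminergic mutants share dopaminergic mutant replicate 3. A low-yield library on that array is a candidate explanation for part of this. Control probe sets for the BioB spike measured a mean of 12.93 there, against 10.74 to 11.61 on the other arrays. A low yield could give this, but the Cre spike hardly differed (14.10 there, 13.86 to 14.10 elsewhere). The SD over probe sets was 1.38 there and 1.76 to 2.06 elsewhere. Without that array 0 of the 10 lists stayed called, while leaving out any other dopaminergic array kept at least 5, but a call can also end because fewer arrays are left, and the means did not shrink alike. For 6 lists less than 50% of the mean was left, as for dopamine (−2.13, SD over genes 0.64, to −0.14, SD 0.87). For 4 lists more was left, and for these the lost call does not support a low yield: Kenyon cell genes (−1.72, SD 0.70, to −1.10, SD 0.90), mitochondrial ribosomal proteins (0.40, SD 0.97, to 0.28, SD 1.16), the TCA cycle (−0.88, SD 1.54, to −0.54, SD 1.56) and autophagy and lysosome (−0.88, SD 1.49, to −0.47, SD 1.35). The means left do not speak against a low yield either. Dopaminergic mutant replicate 1, which lost the next most bright probe sets (29 of 319), stays in the group. Compared with the mean of the other 5 dopaminergic arrays, probe sets at or above a log2 value of 12 were lower there by a median of −5.37, and those under 7 were higher by medians of 0.61 to 0.75, so a list of dim genes would be raised by that array alone. A cholinergic sample under the wrong label stays open. The mean of ChAT, VAChT and ChT was 5.46 there, a difference of −2.53 from the lowest of the 6 cholinergic arrays (7.99 to 10.92), but the loss of bright probe sets on that array would lower these genes in either sort, and the dopaminergic controls (9.50 to 10.86) lie in the cholinergic range. Cells of another type also stay open. Photoreceptor markers were higher there than the mean of the other 5 dopaminergic arrays by a median of 1.21. Beyond probe sets of like level the median was only 0.52. The gene trp measured 8.58 against a mean of 7.34 on those 5 arrays. Only 10 of 19 photoreceptor genes had a named probe set, and ninaE and Rh2 to Rh6 had none. The gate on green fluorescence should remove such cells. A loss of dopamine or synaptic transcripts in mutant neurons stays open. Without that array the mean of the dopamine list was −0.14 and that of the synaptic list −0.36, but Syn (−3.44), Snap25 (−2.64) and unc-13 (−1.60) stayed lower without passing. These 3 values rest on dopaminergic mutant replicate 1 (2.92, 5.72 and 6.10). On replicate 2 the 3 genes were not below the lowest control (9.82, 11.58 and 11.45). For brp the difference was −0.59 without dopaminergic mutant replicate 3. On dopaminergic mutant replicate 1 ple was low as well (7.01), while Ddc (11.37), Pu (11.66) and DAT (9.77) lay within the range of the controls and Vmat measured 12.71 (12.72 to 12.82 in controls).

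For each comparison of 3 arrays with 3, the 10 splits are too few for a share under 0.05. The real value and the highest other were 0 and 8 for probe sets and 10 and 10 for lists in dopaminergic mutants, 6 and 6 for probe sets and 0 and 0 for lists in cholinergic mutants, and 0 and 3 for probe sets and 1 and 0 for lists between neuron types in controls. For the average over neuron types, chance cannot be excluded for lists (65 of 100 splits gave as many; real value 1, highest other 9), and the splits say nothing for probe sets, since all 100 reach the real value of 0 by construction (highest other 11).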

How the results depend on the processing

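Leaving out dopaminergic mutant replicates 1 and 3 together, and an estimated correlation without dopaminergic mutant replicate 3, were added after seeing the data. The first leaves 1 array in that group, which is assumed to vary like the others. Apart from these named settings the cause was not tested. Probe sets called in dopaminergic mutants (0) numbered 1 without a filter, 524 with array weights (mostly that of dopaminergic mutant replicate 1 among the mutants), 33 without both replicates and 0 to 74 leaving out 1 array at a time. In cholinergic mutants (6) they numbered 0 with a filter at the 65th percentile, 2 without a trend, 0 with the D codes or the code letter as a block, 3 with only the 6 arrays compared, 1 without both replicates and 0 to 14 leaving out 1 array at a time. For the difference of the effects (0) the range leaving out 1 array was 0 to 3. Between neuron types in controls (0) the number was 1 without a filter, 6 with array weights, 1 with only the 6 arrays, 3 without both replicates, 2 when mutants were compared in place of controls, and 0 to 5 leaving out 1 array at a time. For the average (0) it was 2 with centred arrays, without a filter, without a trend, with the mean of a gene's probe sets or at a threshold of 0.1, 3 with array weights and 0 to 11 leaving out 1 array at a time. Lists called in dopaminergic mutants (10) numbered 0 with an estimated correlation, with fry, without both replicates and with an estimated correlation without dopaminergic mutant replicate 3, and 0 to 11 leaving out 1 array. In cholinergic mutants (0) they numbered 1 without both replicates and 0 to 1 leaving out 1 array. For the difference (4) they numbered 2 with centred arrays, 7 without a filter, 1 with the D codes as a block, 0 without both replicates, with an estimated correlation (with all arrays or without dopaminergic mutant replicate 3) and with fry, and 0 to 7 leaving out 1 array. Between neuron types (1) they numbered 0 with an estimated correlation or fry with all arrays, 1 with an estimated correlation without dopaminergic mutant replicate 3 (adjusted p = 0.0178) and 1 to 1 leaving out 1 array. For the average (1) they numbered 0 with the D codes as a block, with fry and with an estimated correlation (with or without dopaminergic mutant replicate 3), 2 without both replicates and 1 to 9 leaving out 1 array. Named genes changed sign in 17 cases. With mutants in place of controls the difference between neuron types was −1.12 for Oct-TyrR, −0.24 for trus, 0.064 for E(spl)m5-HLH, 1.28 for fs(1)K10, −0.86 for Ddc and −1.30 for ChAT, which was −0.53 averaged over genotypes and −0.069 with the code letter as a block. For ChAT it ranged from −0.13 to 0.93 leaving out 1 array, negative without cholinergic control replicate 3 (−0.11) and dopaminergic control replicates 1 (−0.084) and 3 (−0.13). In dopaminergic mutants the code letter as a block gave 0.80 for Vmat, 0.63 for DAT and 0.25 for sNPF, and leaving out 1 array gave −3.82 to 0.039, −2.83 to 0.13 and −3.28 to 0.10, the highest of each without dopaminergic mutant replicate 3. That array alone carries the letter F, so the code letter as a block also takes it out of the comparison. The 2 settings are therefore not independent. Of the other values for named genes, 2606 kept direction and side of the threshold, 67 lost a call and 55 gained one. For lists these numbers were 409, 87 and 17, with 0 reversed. Signal limits what can be seen, since the median SD within groups rose from 0.60 for probe sets under a log2 value of 5 to 1.72 between 9 and 10, then fell to 0.78 at 12 or more. Without dopaminergic mutant replicate 3 it was 0.54, 1.43 and 0.24 at these levels.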

Other observations

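Of the tests below, that of glial cells was chosen after the result was seen, and the positions of the called genes and the count of oxidative genes were also looked up afterwards. The genes of the next 2 paragraphs were also chosen after their values were seen.

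Some genes were high on some arrays of a group and near background on others. The GABA synthesis gene Gad1 measured 2.63, 9.76 and 11.18 on the 3 dopaminergic control arrays, was also low on dopaminergic mutant replicates 1 (3.71) and 3 (3.59) and lay at or above 7.88 on the other arrays. The peptide gene Dh44 measured 7.30, 2.38 and 11.02 on the cholinergic controls. BomS2, which encodes an immune-induced peptide, measured 8.29 on cholinergic control replicate 1, 6.98 on cholinergic mutant replicate 1 and 9.66 on dopaminergic mutant replicate 2, and 2.63 to 3.99 elsewhere. In contrast fru, a regulator of sexual behaviour, measured 8.23 to 10.48 on all 12 arrays.

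Some genes known from glia or from oxidative defence were high on dopaminergic mutant replicate 1. The GABA transporter gene Gat measured 12.15 there, the glutamine synthetase gene Gs2 11.71 and axo 11.16, against 9.80, 9.88 and 9.89 as the highest of 10 other arrays, with dopaminergic mutant replicate 3 not counted. The extracellular superoxide dismutase gene Sod3 measured 10.43 (4.37 to 8.31 elsewhere) and the glutathione transferase gene GstD1 11.01 (4.68 to 7.25 elsewhere). Of 36 genes of oxidative stress and glutathione, 28 were higher there than the mean of those 10 arrays and 8 lower (median 0.42), on an array whose median over all probe sets was also above those of the 10 (6.004, against 5.59 to 5.91), and 6 were highest on this array against 12 on dopaminergic mutant replicate 3. Glial cells in the sort are a candidate source, although the gate on green fluorescence should remove them. The median difference over 15 glial genes was only 0.0375, but 5 of them were highest there, against at most 3 on any other array, while repo (2.49) and Gli (3.53) were low, so members going both ways leave this open.

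The calls in cholinergic neurons mostly concern genes at a high level in all arrays of 1 group alone. A genetic background linked to parkin could produce this and stays open. If the dopaminergic mutants carried the same background, its effects could show there too. The means in dopaminergic controls and mutants were 4.02 and 4.55 for CG32246 and 4.98 and 5.14 for lncRNA:CR33942. They were 5.36 and 5.60 for Sps2 and 4.62 and 4.84 for E(spl)m5-HLH. For these genes such a background would have to act in cholinergic neurons alone. Vps11 was lower in dopaminergic mutants as well (5.42 and 3.36). The median absolute t statistic of the 200 genes nearest to parkin (0.770, against 0.715 over all genes) lay at the 78.7th percentile of 653 windows, short of the bound set beforehand, but a median over 200 genes would not move if a few linked genes differed. Of the 5 named genes, Vps11 lies 1.95 megabases from parkin, just outside those 200 (the 263rd nearest tested gene on its chromosome arm), CG32246 lies 16.57 megabases away and E(spl)m5-HLH on the other arm of that chromosome, while Sps2 and lncRNA:CR33942 lie on a different chromosome. Since 3304 of 7562 tested genes lie on the chromosome of parkin, 3 of 5 there is little more than their share. A background difference elsewhere in the genome was not tested. Chance cannot be excluded: of 220 sets of 3 arrays, 25 had as many probe sets standing at least 2 log2 units apart from the other 9 arrays as the cholinergic mutants (real value 4, highest other 34), 161 as many as the cholinergic controls (1) and 86 as many as the dopaminergic controls (2). For the dopaminergic mutants the value was 0, which all 220 sets reach by construction. The set with 34 was cholinergic control replicate 2 with dopaminergic mutant replicates 1 and 3, which points to a structure of the arrays that does not follow the groups and whose cause was not tested. These 3 arrays had the fewest bright probe sets.

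The estimated mutant effects in the 2 neuron types were hardly correlated. Across 7613 genes, which are not independent, r was −0.08 and the sign was the same for 41.4%. Without dopaminergic mutant replicate 3 the values were 0.01 and 50.1%. With all arrays the median effects had opposite signs (0.18 and −0.17), which lowers the share of equal signs. Each effect had a median SE of 0.785, and errors of this size bring r nearer to 0. Whether the true effects are shared therefore stays open.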
